A study of Arabidopsis thaliana with 15 samples.

How the data were processed

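Root RNA of Arabidopsis thaliana (ecotype Columbia-0, wild type) was measured in 15 libraries, 3 biological replicates in each of 5 groups. Per the labels, a replicate held 30 to 50 seedlings, 7 days old, grown in cycles of 16 h light and 8 h dark at 21 °C. The seedlings were placed in aqueous solution, roots and shoots were separated after the treatment, and RNA was extracted from each. Libraries were made with MARS-seq, which reads transcripts near their 3′ end, and sequenced on an Illumina NextSeq. The light during the treatment is not given in the sources used here.

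The authors' processing notes name bcl2fastq, cutadapt, STAR 2.4.2a, HTSeq and DESeq2. Their settings, the genome build, the annotation and whether molecular identifiers were collapsed are not given in the sources used here, so counting intervals and floors cover counting error only. The deposited table holds whole-number read counts (unit: counts) per gene and library for 14391 genes. Each gene in the deposited table has a count of at least 6 in some library, from the values. The authors' deposited table also gives log2 fold changes (unit: log2) of the first-named over the second-named group. It further gives adjusted p values of each comparison (unit: p_value) in columns that the authors label padj, and a yes or no mark of the genes passing the authors' threshold (unit: other). From the values, the genes with the authors' mark have an adjusted p of at most 0.05 and an absolute log2 fold change of at least 1. A further 30 columns per library in the deposited table were not used. Of the loci, 14356 were found in the reference annotation TAIR10.1, used for gene names only, and 35 were not. A symbol was paired with 6474 loci, and the others are named by locus.

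Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 5 groups, which left 9891 genes and set 4500 aside. Scaling was by the trimmed mean of M values (TMM). All 15 libraries entered 1 fit with a coefficient per group, with robust dispersion and quasi-likelihood estimates. The common dispersion was 0.0425, a biological coefficient of variation of 20.6%, with 10 residual degrees of freedom and a median of 13.2 prior degrees of freedom. Each comparison used the two-sided quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 9891 genes. Standard errors (SE) of log2 fold changes were taken as the absolute log2 fold change over the square root of F. CPM are counts scaled to a common library total and use TMM-scaled totals, and log2 CPM for principal components used a prior count of 2.

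The comparisons, tests, gene lists and alternatives were fixed before the data were examined. The comparisons were RB at 1, 2 and 3 h against water, RBH against water, RBH against RB at 2 h, and RB at 3 h against RB at 1 h. The adjacent times (2 h against 1 h, 3 h against 2 h) were added after seeing the table, which also compares them. Named genes were chosen by a fixed rule. Against water, these are the 8 genes with the highest and the 8 with the lowest log2 fold change. In the other 2 comparisons, they are the 5 highest and the 5 lowest. The rule takes called genes with a symbol, a mean count of at least 10 over both groups and CPM ranges that do not overlap, which chance gives in 10% of unchanged genes for 3 against 3 libraries. It also takes from each list up to 4 members with the smallest p in RB 2 h vs water and up to 2 in RBH 2 h vs RB 2 h.

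The gene lists covered singlet oxygen markers, antioxidant enzymes, glutathione transferases and xenobiotic detoxification, heat shock, WRKY and ZAT factors, ERF and DREB factors, jasmonate, auxin, abscisic acid, the endoplasmic reticulum unfolded protein response, cytosolic ribosomal proteins, ribosome biogenesis, salicylate and pattern-triggered immunity, mitochondrial dysfunction, proteases and cell death, hypoxia, aquaporins, nutrient uptake and cell division. Marker sets stood for shoot green tissue, root hair, endodermis, xylem, phloem and root cap. Lists were matched by locus. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over all lists within a comparison. Camera with an estimated correlation and fry served as checks. Some loci stand in 2 lists: ERF5 and ERF6 (ERF and singlet oxygen), WRKY33, RHL41 and STZ (WRKY and singlet oxygen), DREB2A (ERF and heat shock), AT5G51440 (heat shock and mitochondrial), BCS1 (mitochondrial and singlet oxygen) and BAP1 (protease and singlet oxygen).

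A fold against a group with 0 counts is given as a bound, with a floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio is given with its 95% exact binomial counting interval. Library totals ran from 897728 to 6230975 counts, so 1 count was 0.160 to 1.11 CPM and the floor of 3 counts in 1 library 0.481 to 3.34 CPM. In the replicate pairs, the chi-square per degree of freedom ran from 3.42 to 12.4, more than counting error alone gives.

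The test was checked on simulated data with the real totals and dispersions of 9891 genes. In RB 2 h vs water it recovered 34% of 2-fold and 78% of 4-fold changes, with 3 false calls of 115. In RBH 2 h vs RB 2 h it recovered 50% and 80%, with 13 false of 143. For the overlap of comparisons that share the water libraries, all 15 libraries were drawn 20 times from the mean profile of water, with the real totals and dispersions, so that the deviation of the water libraries entered each comparison. The alternatives tried were DESeq2 1.42.0, relative log expression (RLE) scaling, no filter, a filter of 10 CPM in 3 libraries, only the compared groups, the replicate letter as a block, thinning to 897728 counts, a fold threshold, and leaving out each library. Fits added after seeing the data left out the 2 libraries apart on component 3, organelle genes or the 100 most abundant genes. Others had a shoot score as a covariate, for gene counts only as deviations from group means. The replicate letters did not pair the libraries across groups. Same-letter libraries had a median correlation of within-group deviations of -0.066 (-0.299 to 0.271, across genes, which are not independent replicates), and 3 of 15 libraries were closest to one of their own letter. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.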

Results

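The study exposed seedlings of Arabidopsis thaliana, a small flowering plant of the mustard family, to Rose Bengal (RB) and hydrogen peroxide (H2O2) and measured root RNA. RB is a dye that in light passes energy to oxygen and makes singlet oxygen, while H2O2 is a different reactive oxygen species. The 15 libraries fell into 5 groups of 3 biological replicates. They were water for 1 h, 10 µM RB for 1 h, for 2 h and for 3 h, and the combined treatment (RBH) for 2 h. The label of the RBH samples reads 5 mM H2O2 with 10 µM MRB, and what MRB stands for is not given in the sources used here. The water libraries are labelled as exposed for 1 h while their titles say 0. At 2 h and 3 h, treatment and time in solution therefore changed together against water. Roots in H2O2 alone, which the treatment text mentions, were not analysed here.

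Library totals were 897728 to 1897364 counts in water, 1061356 to 3059488 in RB 1 h, 1032423 to 2305295 in RB 2 h, 1364525 to 4389349 in RB 3 h and 1500423 to 6230975 in RBH 2 h. Means are given ± SD in CPM, counts scaled to a common library total, with n = 3 libraries per group throughout. On principal component 1, with 42.5% of the variance, the water libraries scored -74.57 to -60.16 and RB 1 h -35.85 to -20.80. RB 2 h scored 13.46 to 29.65, RB 3 h 34.01 to 42.54 and RBH 29.29 to 37.47. The RBH libraries stood apart on component 2 (16.1%), at 41.55 to 46.77 against at most 10.42 in the others. Replicate b of RB 1 h (-30.23) and replicate a of RB 2 h (-46.83) lay apart on component 3 (7.40%), where the other libraries scored -12.09 to 18.97. ATMG00020, the mitochondrial 26S ribosomal RNA locus, took 3.16 ± 0.314% of counts in water, 2.04 ± 0.791% in RB 1 h, 1.96 ± 0.455% in RB 2 h, 1.81 ± 0.484% in RB 3 h and 1.14 ± 0.297% in RBH.

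**Figure D1:**
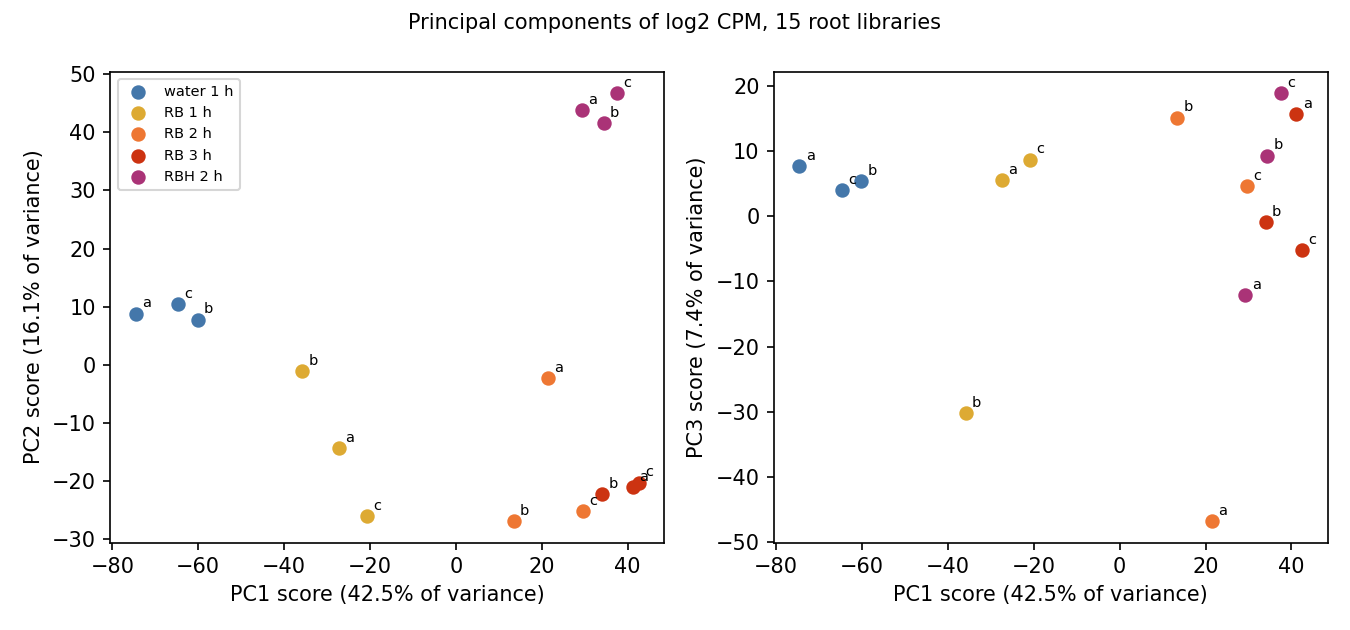
Scores of the 15 libraries on principal components 1, 2 and 3 of log2 CPM, with points coloured by group and lettered by replicate. Along component 1 the RB groups lie in the order of exposure time, and on component 2 the RBH libraries lie at 41.55 to 46.77.

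**Figure D2:**
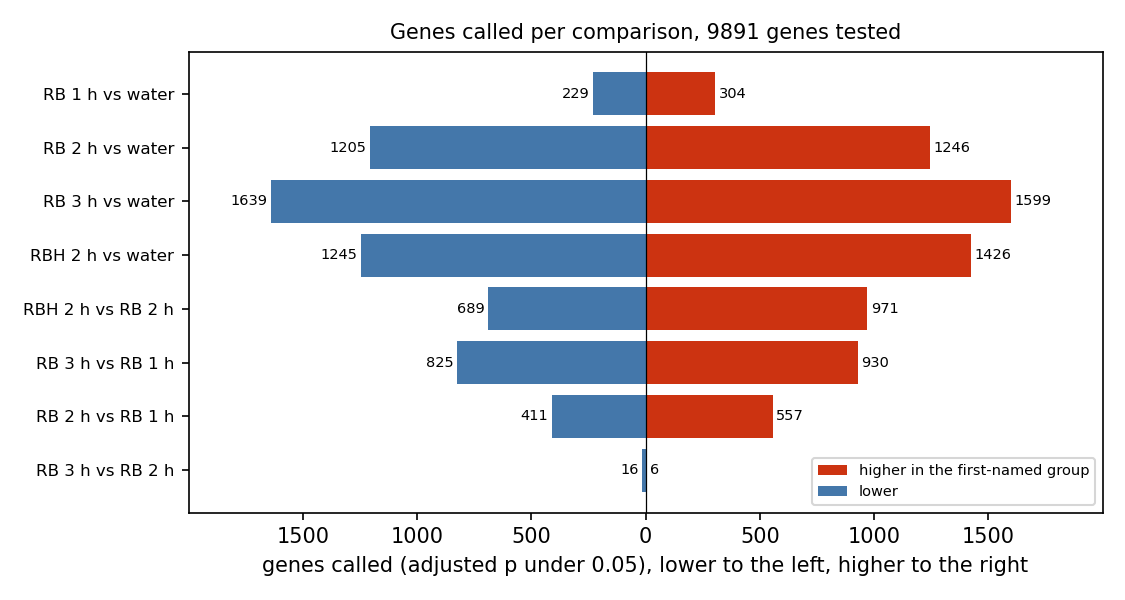
Number of genes called in each comparison (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 9891 genes tested), drawn to the right for genes higher in the first-named group and to the left for lower ones. The RB comparisons with water hold 533, 2451 and 3238 genes at 1, 2 and 3 h.

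The comparison of RB 1 h with water, the one with water at a matched time by the labels, asked which genes respond first to the dye. Of the fixed lists, 16 of 22 heat shock genes and 8 of 10 markers of singlet oxygen were higher after RB. HSP17.4 (AT3G46230), a small heat shock protein that holds unfolding proteins, rose from 13.7 ± 2.80 to 190 ± 40.7 CPM (log2 fold change 3.82, SE 0.26, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.92e-10). NRT2:1 (AT1G08090), a high-affinity nitrate transporter, fell from 145 ± 6.59 to 15.5 ± 6.54 CPM (-3.23, SE 0.30, adjusted p = 1.99e-07). In all, 533 of 9891 genes were called, 304 higher and 229 lower, of which 257 and 125 changed at least 2-fold.

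Among the fixed lists at 1 h, 16 of 22 heat shock genes rose (17 adjusted over the list alone, median log2 fold change 2.49, 2.80 with genes at their bound and 2 members without a bound left out, camera adjusted p = 2.02e-43). HSP17.6A (AT5G12030) rose from 4.79 ± 2.94 to 93.0 ± 25.7 CPM and BAG6 (AT2G46240), a co-chaperone, from 1.82 ± 1.87 to 30.4 ± 7.40 CPM, while HSP18.2 (AT5G59720) did not pass (6.19 ± 0.627 CPM against 8.76 ± 2.64). Of the singlet oxygen markers, 8 of 10 rose (10 adjusted over the list alone, median 2.07, adjusted p = 4.3e-26). AT1G19020, a marker without a symbol, rose from 93.5 ± 10.8 to 686 ± 73.9 CPM, and ERF6 (AT4G17490), an ethylene-response transcription factor, from 119 ± 21.7 to 490 ± 109 CPM. Both calls held with an estimated correlation (adjusted p = 0.00487 and 0.00205). Of the glutathione transferase and detoxification genes, whose enzymes couple foreign compounds to glutathione or sugars, 7 of 26 rose (11 adjusted over the list alone, median 1.15, 1.07 with genes at their bound and 2 left out, adjusted p = 1.2e-08, and adjusted p = 0.181 with an estimated correlation). GSTU12 (AT1G69920) rose from 1.48 ± 0.909 to 31.5 ± 13.4 CPM and OPR1 (AT1G76680), an oxophytodienoate reductase, from 113 ± 16.6 to 299 ± 30.3 CPM.

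Some stress transcription factors rose as well at 1 h. Of the WRKY and ZAT factors, 7 of 14 rose (11 rose and 1 fell adjusted over the list alone, median 1.06, 0.92 with genes at their bound, adjusted p = 3.33e-10, and adjusted p = 0.0556 with an estimated correlation). WRKY33 (AT2G38470), a regulator of defence, rose from 47.6 ± 22.8 to 248 ± 88.7 CPM and ZAT6 (AT5G04340) from 231 ± 11.3 to 615 ± 85.3 CPM. Of the ERF and DREB factors, 9 of 19 rose and 1 fell (9 and 3 adjusted over the list alone, median 0.85, 0.76 with genes at their bound and 1 left out, adjusted p = 2.17e-06, and adjusted p = 0.181 with an estimated correlation). ERF2 (AT5G47220) rose from 14.8 ± 5.74 to 62.4 ± 22.3 CPM. In the salicylate and immunity list 5 of 12 rose and 1 fell (6 and 1 adjusted over the list alone, median 1.02, adjusted p = 0.00191, and adjusted p = 0.181 with an estimated correlation). PAD4 (AT3G52430), a lipase-like regulator of immunity, rose from 1.86 ± 0.466 to 14.4 ± 4.80 CPM. In the mitochondrial dysfunction list, 2 of 9 rose (4 adjusted over the list alone, median 1.14, 0.80 with genes at their bound and 1 left out, adjusted p = 0.00188, and adjusted p = 0.181 with an estimated correlation), among them BCS1 (AT3G50930), an outer mitochondrial membrane ATPase.

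Aquaporins, the water channels, were lower as a list at 1 h, with 2 of 10 called lower (6 adjusted over the list alone, median -0.58, adjusted p = 1.7e-05, and adjusted p = 0.279 with an estimated correlation). TIP2;2 (AT4G17340) of the vacuolar membrane fell from 2683 ± 220 to 1362 ± 323 CPM. In the list of the unfolded protein response of the endoplasmic reticulum, 4 of 13 fell (5 adjusted over the list alone, median -0.26, mean 0.04, adjusted p = 0.0381, and adjusted p = 0.351 with an estimated correlation or 0.141 with the shoot score as a covariate). The chaperone BIP2 (AT5G42020) fell from 1341 ± 70.6 to 756 ± 72.4 CPM. Shoot green tissue markers were lower too, with 2 of 16 called (7 adjusted over the list alone, median -0.70, adjusted p = 6.32e-05, and adjusted p = 0.351 with an estimated correlation, or 0.0815 with fry). Their share of counts was 0.0537% to 0.139% over all libraries. The camera test did not pass for jasmonate synthesis and signalling (0 higher and 2 lower of 22, adjusted p = 0.366) and auxin response and transport (0 higher and 0 lower of 18, adjusted p = 0.226). It also did not pass for abscisic acid and dehydration (0 higher and 1 lower of 16, adjusted p = 0.622) and cytosolic ribosomal proteins (0 higher and 0 lower of 29, adjusted p = 0.0839). No list call was made for ribosome biogenesis (0 higher and 0 lower of 11, adjusted p = 0.468) and proteases and cell death regulators (3 higher and 0 lower of 13, adjusted p = 0.156). The threshold was not reached by the core hypoxia response (0 higher and 0 lower of 14, adjusted p = 0.222) and root nutrient uptake (4 higher and 5 lower of 14, adjusted p = 0.0516). Further lists without a call were antioxidant enzymes (0 higher and 0 lower of 18, adjusted p = 0.869) and cell division (0 higher and 0 lower of 2, adjusted p = 0.366). The same was found for root hair markers (0 higher and 0 lower of 4, adjusted p = 0.343) and endodermis markers (0 higher and 0 lower of 5, adjusted p = 0.401). Likewise not called were xylem markers (0 higher and 0 lower of 2, adjusted p = 0.869), phloem markers (0 higher and 0 lower of 3, adjusted p = 0.983) and root cap markers (0 higher and 0 lower of 1, adjusted p = 0.869). Adjusted over the list alone, these counts were the same except 4 higher and 6 lower for root nutrient uptake and 1 higher and 0 lower for cell division. Medians and tests differed in sign for abscisic acid (median 0.01, mean -0.04) and for phloem (0.05 beside a downward test). In nutrient uptake the genes that fell were transporters and a nitrite reductase, with PHT1;1 (AT5G43350), a phosphate transporter, from 1213 ± 193 to 309 ± 36.0 CPM. Those that rose act in nitrate reduction and sulfur nutrition, with LSU1 (AT3G49580) from 8.90 ± 6.14 to 68.8 ± 19.2 CPM.

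Genes named by the fixed rule are not ranked here, since folds over 0 or few counts are bounds or wide intervals. At 1 h HSP23.6-MITO (AT4G25200), a mitochondrial small heat shock protein, was at least 23.3-fold higher (18.7 ± 8.22 CPM, 0 counts in water). IGMT4 (AT1G21130), an indole glucosinolate methyltransferase, was 81.6-fold higher (95% counting interval 14.4 to 3250), and its close paralog IGMT2 (AT1G21120) rose from 4.37 ± 1.39 to 88.9 ± 38.5 CPM. The zinc finger factor ZAT11 (AT2G37430) rose from 1.15 ± 1.12 to 12.2 ± 5.24 CPM. Named for their falls were NAS1 (AT5G04950), a nicotianamine synthase, from 23.0 ± 1.44 to 4.33 ± 2.29 CPM, the laccase LAC7 (AT3G09220), from 38.4 ± 14.4 to 8.65 ± 1.52 CPM, and the ammonium transporter AMT1;3 (AT3G24300), from 52.4 ± 11.1 to 13.7 ± 6.18 CPM. PR-1-LIKE (AT2G19990), RAS1 (AT1G09950) and the molybdate transporter MOT1 (AT2G25680) fell by 2.03, 1.96 and 1.94 on the log2 scale. In 5, 4 and 5 of the 6 fits without 1 library their calls were lost, with adjusted p over all alternatives of 0.00878 to 0.268, 0.0115 to 0.470 and 0.0230 to 0.147. The fall of RAS1 in RB 1 h vs water was carried by 1 library, at a log2 fold change of -0.767 (adjusted p = 0.470) without water replicate b. Counts of close paralogs, here IGMT2 and IGMT4, the GSTU genes, UGT73B4 and UGT73B5, and the HSP17.6 family, can be shared or split by read counting, so single members are uncertain. The count of 533 genes moved to 348 without water replicate a, 296 without water c, 312 without RB 1 h a, 331 without RB 1 h c, and 1104 without the 2 libraries apart on component 3. Its balance of 304 higher and 229 lower moved to 219 and 93 without RB 1 h a, 222 and 109 without RB 1 h c, 270 and 152 without water b, and turned to 510 higher and 594 lower without the 2 libraries apart. The authors' deposited table marked 357 genes at 1 h, 240 higher and 117 lower after RB, all changed at least 2-fold. At that fold 382 were called here.

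After 2 h of RB, every heat shock gene tested was higher than in 1 h water, 25 of 26 detoxification genes rose with them, and all 10 aquaporins and 4 root hair markers were lower. The calls of the latter lists were lost with an estimated correlation (adjusted p = 0.0711 and 0.197). HSP17.4 rose from 13.7 ± 2.80 to 1392 ± 278 CPM (log2 fold change 6.70, SE 0.27, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.38e-14), and OPR1 from 113 ± 16.6 to 1704 ± 556 CPM (3.90, SE 0.22, adjusted p = 9.18e-12). TIP2;2 fell from 2683 ± 220 to 449 ± 77.0 CPM (-2.58, SE 0.24, adjusted p = 1.96e-08). In all, 2451 genes were called, 1246 higher and 1205 lower, of which 915 and 691 changed at least 2-fold.

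By list at 2 h, 22 of 22 heat shock genes rose (22 adjusted over the list alone, median 5.36, 4.82 with genes at their bound, camera adjusted p = 1.69e-71). AT1G53540, a small heat shock protein, rose from 5.47 ± 2.20 to 517 ± 52.6 CPM. Of the detoxification genes, 25 of 26 rose (26 adjusted over the list alone, median 3.76, 3.40 with genes at their bound, adjusted p = 5.58e-32). UGT75B1 (AT1G05560), a glucosyltransferase, was 138-fold higher (95% counting interval 47.1 to 673), and CYP81D8 (AT4G37370), a cytochrome P450, 62.3-fold higher (95% counting interval 17 to 519). All 10 singlet oxygen markers rose (10 adjusted over the list alone, median 2.96, adjusted p = 2.92e-21). RHL41 (AT5G59820), the zinc finger factor also known as ZAT12, rose from 173 ± 56.3 to 914 ± 157 CPM. Of the WRKY and ZAT factors 11 of 14 rose (11 adjusted over the list alone, median 1.88, adjusted p = 2.71e-10). ERF and DREB factors rose in 13 of 19 cases (14 higher and 1 lower adjusted over the list alone, median 1.90, adjusted p = 1.62e-11). WRKY6 (AT1G62300) rose from 71.2 ± 3.77 to 299 ± 17.3 CPM and ERF-1 (AT4G17500) from 214 ± 33.0 to 1218 ± 291 CPM. In the salicylate and immunity list 7 of 12 rose (7 adjusted over the list alone, median 1.85, adjusted p = 9.55e-06). MKK9 (AT1G73500), a kinase, rose from 133 ± 18.7 to 822 ± 191 CPM. In the mitochondrial dysfunction list 7 of 9 rose (8 adjusted over the list alone, median 2.57, 1.65 with genes at their bound, adjusted p = 8.11e-08). The alternative oxidase AOX1A (AT3G22370) rose from 15.1 ± 1.99 to 144 ± 64.8 CPM. These 7 calls held with an estimated correlation, at adjusted p = 0.0023 for heat shock to 0.0477 for salicylate and immunity.

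Further lists passed camera at 2 h and not with an estimated correlation. All 10 aquaporins fell (10 adjusted over the list alone, median -1.49, adjusted p = 6.37e-11, and adjusted p = 0.0711 with an estimated correlation). PIP2A (AT3G53420) of the plasma membrane fell from 2498 ± 107 to 936 ± 182 CPM. All 4 root hair markers fell (4 adjusted over the list alone, median -2.51, adjusted p = 0.003, and adjusted p = 0.197 with an estimated correlation). The expansin EXPA18 (AT1G62980) fell from 49.4 ± 13.9 to 10.2 ± 2.91 CPM. Of the unfolded protein response genes 7 of 13 fell and 2 rose (7 and 2 adjusted over the list alone, median -0.89, adjusted p = 0.000249, and adjusted p = 0.0945 with an estimated correlation). CNX1 (AT5G61790), the lectin chaperone calnexin, fell from 1369 ± 167 to 360 ± 26.7 CPM and BIP2 from 1341 ± 70.6 to 423 ± 30.9 CPM. Hypoxia genes rose in 5 of 14 cases (6 adjusted over the list alone, median 0.47, adjusted p = 0.0373, and adjusted p = 0.299 with an estimated correlation). HB1 (AT2G16060), a haemoglobin, rose from 50.2 ± 4.03 to 184 ± 42.3 CPM. Protease and cell death genes rose in 4 and fell in 1 of 13 (4 and 1 adjusted over the list alone, median 0.39, adjusted p = 0.0336, and adjusted p = 0.0762 with an estimated correlation or 0.0552 without the 2 libraries apart on component 3). BAP2 (AT2G45760), which restrains cell death, rose from 1.34 ± 0.845 to 18.8 ± 8.22 CPM. Cytosolic ribosomal proteins fell in 5 of 29 cases (5 adjusted over the list alone, median -0.28, adjusted p = 0.0373, and adjusted p = 0.462 with an estimated correlation). Ribosome biogenesis genes fell in 4 of 11 (5 adjusted over the list alone, median -0.45, adjusted p = 0.0359, and adjusted p = 0.299 with an estimated correlation). NUC-L1 (AT1G48920), a nucleolin, fell from 786 ± 23.1 to 476 ± 68.8 CPM. The camera test did not pass for jasmonate synthesis and signalling (2 higher and 2 lower of 22, adjusted p = 0.456) and auxin response and transport (2 higher and 1 lower of 18, adjusted p = 0.606). It also did not pass for abscisic acid and dehydration (5 higher and 3 lower of 16, adjusted p = 0.428) and root nutrient uptake (6 higher and 6 lower of 14, adjusted p = 0.606). No list call was made for antioxidant enzymes (4 higher and 1 lower of 18, adjusted p = 0.265) and cell division (0 higher and 0 lower of 2, adjusted p = 0.52). The threshold was not reached by shoot green tissue markers (0 higher and 2 lower of 16, adjusted p = 0.284) and endodermis markers (0 higher and 1 lower of 5, adjusted p = 0.456). Further lists without a call were xylem markers (0 higher and 0 lower of 2, adjusted p = 0.68), phloem markers (0 higher and 0 lower of 3, adjusted p = 0.79) and root cap markers (0 higher and 0 lower of 1, adjusted p = 0.919). Adjusted over the list alone, these counts were the same except 2 higher and 1 lower for jasmonate synthesis and signalling, 5 higher and 1 lower for antioxidant enzymes and 0 higher and 1 lower for shoot green tissue markers. Nutrient uptake had a negative median (-0.25) beside an upward test, and endodermis a positive median (0.17) beside a downward one. In nutrient uptake APR3 (AT4G21990) of sulfate assimilation rose from 24.4 ± 6.24 to 251 ± 49.7 CPM and NIA1 (AT1G77760), a nitrate reductase, from 28.0 ± 6.09 to 458 ± 116 CPM, while PHT1;1 fell from 1213 ± 193 to 105 ± 29.1 CPM.

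Named for their rises at 2 h were HSP23.6-MITO (at least 272-fold higher), UGT74E2 (AT1G05680) (at least 103-fold higher), a glucosyltransferase of the auxin indole-3-butyric acid, ATHSP22.0 (AT4G10250) (at least 19.7-fold higher), HSP70T-2 (AT2G32120) (at least 17.1-fold higher) and GSTU25 (AT1G17180) (at least 14.5-fold higher), each with 0 counts in water. The call of GSTU25 was lost without water replicate c (adjusted p = 0.0607) and without RB 2 h replicate c (0.0618), with 0.000182 to 0.0647 over all alternatives. GSTU12 rose from 1.48 ± 0.909 to 252 ± 84.0 CPM, HSP17.6A from 4.79 ± 2.94 to 845 ± 200 CPM, and THA1 (AT1G08630), a threonine aldolase, was 194-fold higher (95% counting interval 34.5 to 7680). Named for their falls at 2 h were NRT2:1 (397-fold lower, counting interval 109 to 3280), NAS1 (42.6-fold lower, counting interval 14.1 to 210), GDU4 (AT2G24762) (from 79.8 ± 13.9 to 4.36 ± 3.33 CPM) and cell wall proteins of the extensin family. Of these EXT6 (AT2G24980) was 69.5-fold lower (95% counting interval 18.7 to 582), and EXT10 (AT5G06640) fell from 39.8 ± 19.3 to 1.78 ± 1.28 CPM. HRGP1 (AT3G54590) fell from 80.0 ± 26.9 to 3.57 ± 4.16 CPM, and EXT11 (AT5G49080) and EXT13 (AT5G35190) had log2 fold changes of -5.21 and -4.47. The extensins are close paralogs, so their single values are uncertain. Without 1 library at a time the count of 2451 ran from 1707 to 2657, with 919 higher and 788 lower without RB 2 h replicate c. The authors' deposited table marked 1434 genes at 2 h, 796 higher and 638 lower after RB.

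**Figure D3:**
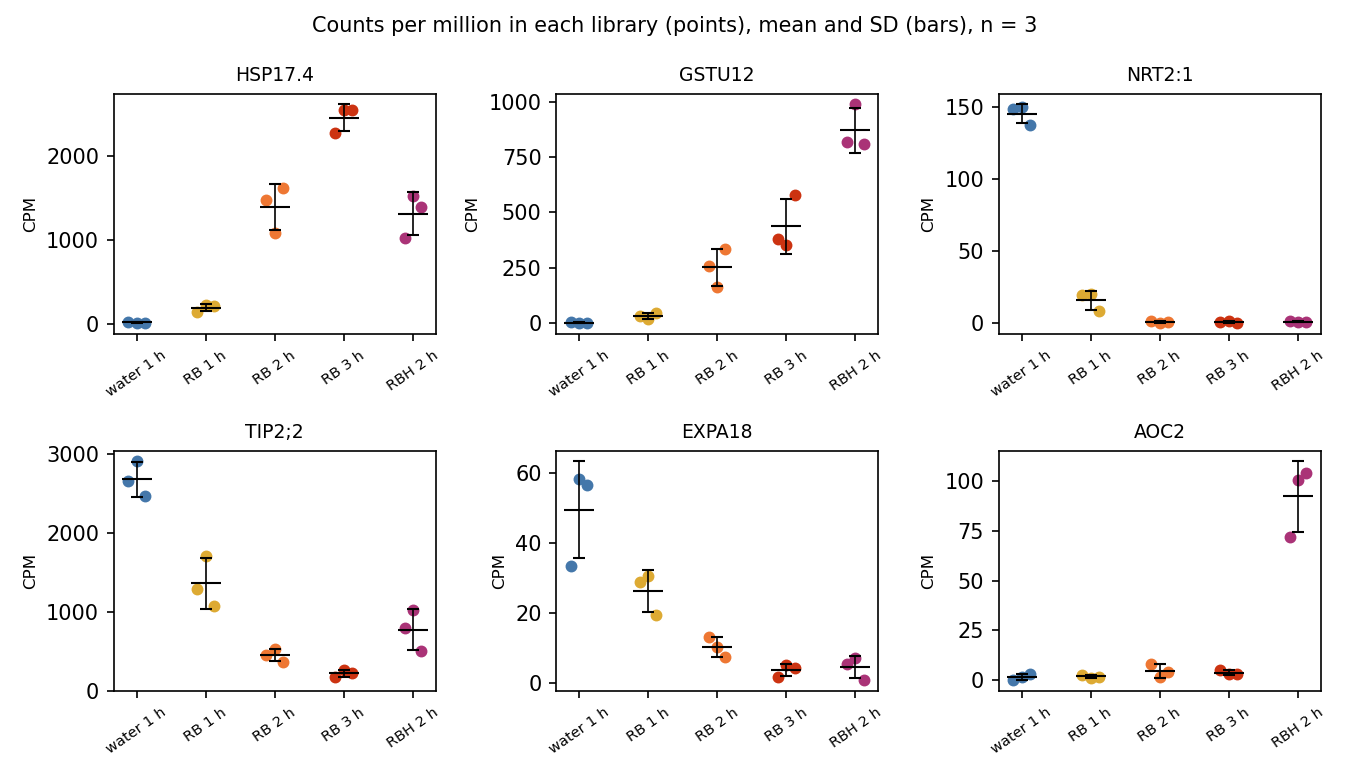
CPM of 6 genes in each library (points) with the group mean and SD (bars, n = 3), on linear axes that start at 0 or just below it. HSP17.4 runs from 13.7 CPM in water to 2453 CPM in RB 3 h, NRT2:1 from 145 to 0.407 CPM, and AOC2 reaches 92.4 CPM in RBH.

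After 3 h of RB, heat shock and detoxification genes had the highest medians of the 3 RB times against 1 h water, and aquaporins and root hair markers the lowest (for root hair, adjusted p = 0.129 with an estimated correlation). HSP17.4 rose from 13.7 ± 2.80 to 2453 ± 160 CPM (log2 fold change 7.51, SE 0.28, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.29e-15). TIP2;2 fell from 2683 ± 220 to 219 ± 43.0 CPM (-3.62, SE 0.25, adjusted p = 1.28e-10) and EXPA18 from 49.4 ± 13.9 to 3.68 ± 1.75 CPM (-3.94, SE 0.48, adjusted p = 1.5e-06). In all, 3238 genes were called, 1599 higher and 1639 lower, of which 1192 and 945 changed at least 2-fold.

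At 3 h 22 of 22 heat shock genes rose (22 adjusted over the list alone, median 5.92, 5.51 with genes at their bound, camera adjusted p = 4.12e-71). Of the detoxification genes 25 of 26 rose (26 adjusted over the list alone, median 4.02, 3.71 with genes at their bound, adjusted p = 1.66e-34). All 10 singlet oxygen markers rose (10 adjusted over the list alone, median 3.33, adjusted p = 2.08e-20). AT1G19020 rose from 93.5 ± 10.8 to 1484 ± 185 CPM and OPR1 from 113 ± 16.6 to 2146 ± 343 CPM. Of the WRKY and ZAT factors 12 of 14 rose (12 adjusted over the list alone, median 2.16, adjusted p = 3.91e-11). ERF and DREB factors rose in 14 of 19 cases (15 adjusted over the list alone, median 2.32, adjusted p = 1.1e-12). Salicylate and immunity genes rose in 10 of 12 (10 adjusted over the list alone, median 2.03, adjusted p = 2.89e-07), and mitochondrial dysfunction genes in 8 of 9 (8 adjusted over the list alone, median 2.63, adjusted p = 2.24e-09). PAD3 (AT3G26830), the last enzyme of camalexin synthesis, rose from 3.18 ± 0.705 to 54.6 ± 15.6 CPM, and AOX1A from 15.1 ± 1.99 to 212 ± 80.3 CPM. All 10 aquaporins fell (10 adjusted over the list alone, median -2.46, adjusted p = 7.47e-18). RD28 (AT2G37180) fell from 300 ± 45.4 to 41.5 ± 7.26 CPM. These 8 calls held with an estimated correlation, at adjusted p = 0.00173 to 0.0205.

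Root hair markers fell in 4 of 4 cases at 3 h (4 adjusted over the list alone, median -3.83, adjusted p = 0.000398, and adjusted p = 0.129 with an estimated correlation). EXPA7 (AT1G12560) fell from 45.6 ± 2.91 to 6.15 ± 4.79 CPM. Shoot green tissue markers were lower in 10 of 16 (10 adjusted over the list alone, median -1.28, adjusted p = 0.000497, and adjusted p = 0.354 with an estimated correlation). PSBO1 (AT5G66570) of photosystem II fell from 129 ± 25.0 to 37.9 ± 4.12 CPM. In the unfolded protein response list 7 of 13 fell and 2 rose (8 and 2 adjusted over the list alone, median -0.60, adjusted p = 0.00774, and adjusted p = 0.218 with an estimated correlation). CNX1 fell from 1369 ± 167 to 445 ± 67.9 CPM. Hypoxia genes rose in 5 of 14 (6 adjusted over the list alone, median 0.66, adjusted p = 0.00896, and adjusted p = 0.218 with an estimated correlation), with ERF71 (AT2G47520) 70.4-fold higher (95% counting interval 23.9 to 343). The camera test did not pass for jasmonate synthesis and signalling (7 higher and 1 lower of 22, adjusted p = 0.122) and auxin response and transport (8 higher and 0 lower of 18, adjusted p = 0.073). It also did not pass for abscisic acid and dehydration (4 higher and 2 lower of 16, adjusted p = 0.452) and cytosolic ribosomal proteins (1 higher and 9 lower of 29, adjusted p = 0.0538). No list call was made for ribosome biogenesis (0 higher and 5 lower of 11, adjusted p = 0.0538) and proteases and cell death regulators (5 higher and 1 lower of 13, adjusted p = 0.0615). The threshold was not reached by root nutrient uptake (6 higher and 6 lower of 14, adjusted p = 0.452) and antioxidant enzymes (4 higher and 2 lower of 18, adjusted p = 0.371). Further lists without a call were cell division (0 higher and 0 lower of 2, adjusted p = 0.972) and endodermis markers (0 higher and 1 lower of 5, adjusted p = 0.27). The same was found for xylem markers (1 higher and 0 lower of 2, adjusted p = 0.371), phloem markers (0 higher and 0 lower of 3, adjusted p = 0.9) and root cap markers (0 higher and 0 lower of 1, adjusted p = 0.852). Adjusted over the list alone, these counts were the same except 9 higher and 1 lower for auxin response and transport, 1 higher and 10 lower for cytosolic ribosomal proteins, 5 higher and 2 lower for proteases and cell death regulators, 5 higher and 2 lower for antioxidant enzymes and 2 higher and 0 lower for xylem markers. Nutrient uptake had a negative median (-0.35) beside an upward test. Among auxin genes, IAA16 (AT3G04730), a repressor of auxin responses, rose from 185 ± 16.8 to 417 ± 23.0 CPM and GH3.1 (AT2G14960), of a family that couples auxin to amino acids, from 6.02 ± 2.26 to 23.2 ± 6.65 CPM.

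Named for their rises at 3 h were HSP23.6-MITO (at least 522-fold higher, 417 ± 59.8 CPM), UGT74E2 (at least 226-fold higher), ATHSP22.0 (at least 39.9-fold higher), GSTU25 (at least 26.3-fold higher) and HSP70T-2 (at least 22.9-fold higher). Also named were HSP17.6A (from 4.79 ± 2.94 to 1563 ± 117 CPM), GSTU12 (from 1.48 ± 0.909 to 436 ± 124 CPM) and HSP17.6II (AT5G12020) (from 2.39 ± 1.47 to 683 ± 63.6 CPM). Named for their falls at 3 h were NRT2:1 (387-fold lower, counting interval 132 to 1880), EXT6 (203-fold lower, counting interval 35.7 to 8110), EXT11 (109-fold lower, counting interval 29.4 to 910) and EXT13 (67.8-fold lower, counting interval 18 to 571). So were XTH12 (AT5G57530), a xyloglucan enzyme of the cell wall (41.8-fold lower, counting interval 13.6 to 208), HRGP1 (from 80.0 ± 26.9 to 0.885 ± 0.619 CPM), EXT10 (from 39.8 ± 19.3 to 1.29 ± 0.804 CPM) and RHS19 (AT5G67400), a peroxidase of root hairs (from 16.1 ± 5.46 to 0.381 ± 0.337 CPM). Without 1 library at a time the count of 3238 ran from 2486 to 2778. The authors' deposited table marked 1991 genes at 3 h, 1124 higher and 867 lower after RB.

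**Figure D4:**
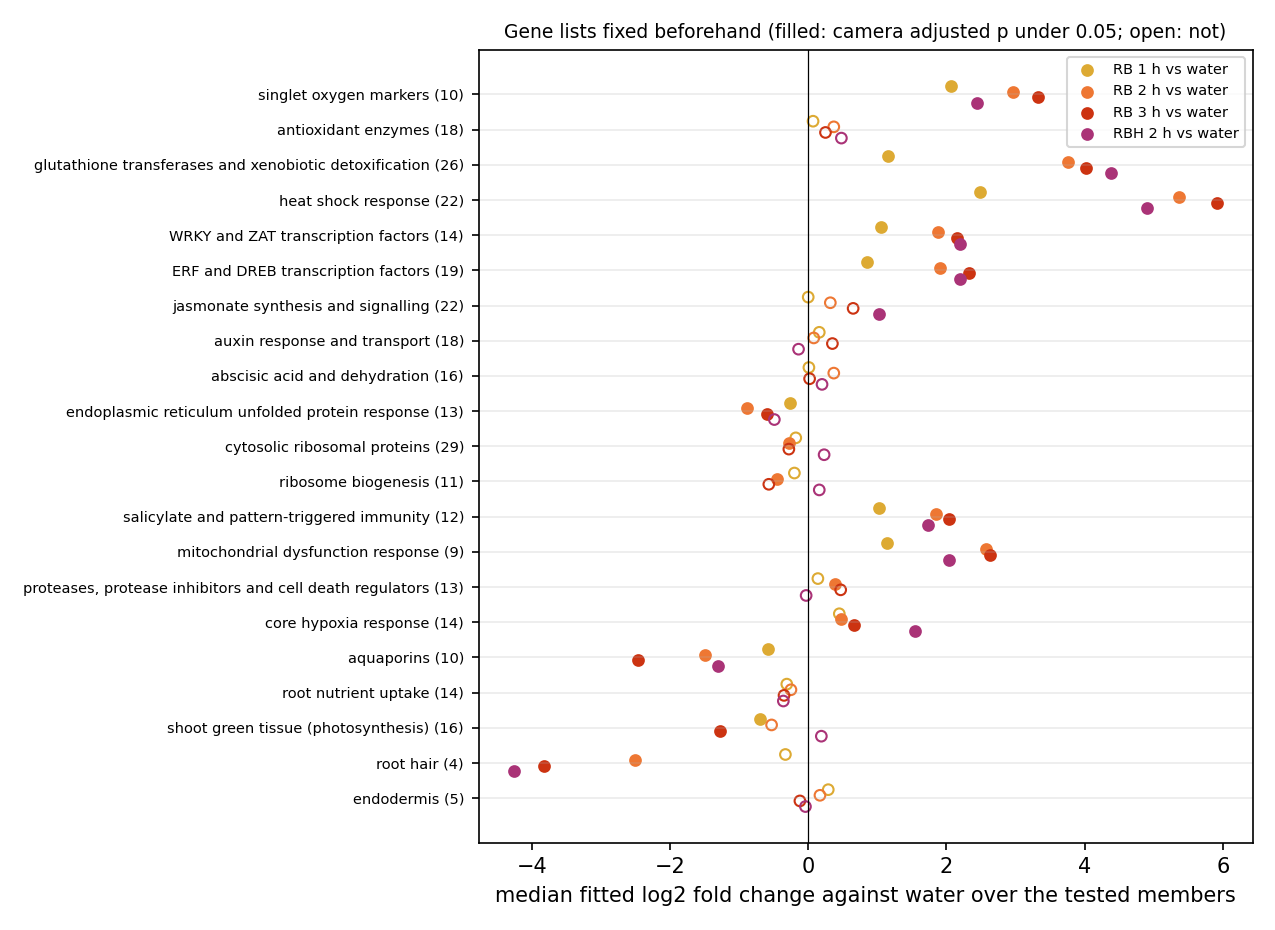
Median fitted log2 fold change against water of each fixed gene list with at least 4 tested members (number in brackets) for RB at 1, 2 and 3 h and RBH at 2 h, with filled points where the camera adjusted p was under 0.05 and open points elsewhere. Heat shock medians run from 2.49 to 5.92 and root hair medians from -0.33 to -4.26.

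RB 3 h was compared with RB 1 h, where dye exposure and time in solution rose together, without water at 3 h. All 22 heat shock genes were higher at 3 h, 23 of 26 detoxification genes rose with them, and all 10 aquaporins and 4 root hair markers were lower (for root hair, adjusted p = 0.0857 with an estimated correlation). Hsp70b (AT1G16030) rose from 10.4 ± 2.34 to 261 ± 41.2 CPM (log2 fold change 4.66, SE 0.27, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.14e-11), and TIP2;2 fell from 1362 ± 323 to 219 ± 43.0 CPM (-2.64, SE 0.24, adjusted p = 2.82e-08). In all, 1755 genes were called, 930 higher and 825 lower at 3 h, of which 616 and 499 changed at least 2-fold. The adjacent times, compared after the table was seen, gave 968 genes between 1 h and 2 h (557 higher, 411 lower) and 22 between 2 h and 3 h (6 higher, 16 lower, with 842 at an unadjusted p under 0.05).

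The heat shock genes had a median log2 fold change of 3.06 at 3 h against 1 h (22 genes adjusted over the list alone, camera adjusted p = 9.33e-72). Of the detoxification genes 23 of 26 rose (23 adjusted over the list alone, median 2.82, adjusted p = 1.14e-44). Singlet oxygen markers rose in 9 of 10 (9 adjusted over the list alone, median 1.20, adjusted p = 1.36e-08). ERF and DREB factors rose in 12 of 19 (14 adjusted over the list alone, median 1.34, adjusted p = 1.49e-11), and mitochondrial dysfunction genes in 7 of 9 (8 adjusted over the list alone, median 1.92, adjusted p = 1.18e-10). In the salicylate and immunity list 8 of 12 rose and 1 fell (9 and 1 adjusted over the list alone, median 1.05, adjusted p = 1.07e-06). GRX480 (AT1G28480), a glutaredoxin, rose from 7.82 ± 1.87 to 87.1 ± 20.2 CPM and NDB2 (AT4G05020), an alternative NADH dehydrogenase, from 28.7 ± 2.52 to 170 ± 12.6 CPM. The aquaporin list fell with a median of -1.86 (10 genes adjusted over the list alone, adjusted p = 1.6e-18). These 7 calls held with an estimated correlation, at adjusted p = 0.00117 to 0.0275.

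Other lists differed between 3 h and 1 h by camera and not with an estimated correlation. Root hair markers fell in 4 of 4 (4 adjusted over the list alone, median -3.26, adjusted p = 3.18e-05, and adjusted p = 0.0857 with an estimated correlation). WRKY and ZAT factors rose in 10 of 14 (10 higher and 1 lower adjusted over the list alone, median 0.99, adjusted p = 4.92e-06, and adjusted p = 0.0942 with an estimated correlation). Jasmonate genes rose in 7 of 22 (7 adjusted over the list alone, median 0.80, adjusted p = 0.00314, and adjusted p = 0.174 with an estimated correlation). Hypoxia genes rose in 4 of 14 (4 adjusted over the list alone, median 0.55, adjusted p = 0.00769, and adjusted p = 0.191 with an estimated correlation). Nutrient uptake genes rose in 6 and fell in 3 of 14 (6 and 4 adjusted over the list alone, median 0.27, adjusted p = 0.00941, and adjusted p = 0.191 with an estimated correlation). Ribosome biogenesis genes fell in 4 of 11 (5 adjusted over the list alone, median -0.47, adjusted p = 0.0317, and adjusted p = 0.255 with an estimated correlation). FIB2 (AT4G25630), a fibrillarin, fell from 225 ± 75.3 to 123 ± 16.9 CPM. Endodermis markers fell in 2 of 5 (3 adjusted over the list alone, median -0.74, adjusted p = 0.0192, and adjusted p = 0.121 with an estimated correlation). CASP1 (AT2G36100), a protein of the Casparian strip, fell from 414 ± 21.6 to 187 ± 7.71 CPM. Unfolded protein response genes fell in 4 and rose in 1 of 13 (5 and 2 adjusted over the list alone, median -0.49, adjusted p = 0.0486, and adjusted p = 0.327 with an estimated correlation, 0.0505 with the replicate block, 0.207 without the 2 libraries apart and 0.0968 with the shoot score). The camera test did not pass for auxin response and transport (4 higher and 2 lower of 18, adjusted p = 0.126) and abscisic acid and dehydration (4 higher and 1 lower of 16, adjusted p = 0.124). It also did not pass for cytosolic ribosomal proteins (0 higher and 1 lower of 29, adjusted p = 0.159) and proteases and cell death regulators (3 higher and 0 lower of 13, adjusted p = 0.126). No list call was made for antioxidant enzymes (3 higher and 1 lower of 18, adjusted p = 0.214) and cell division (0 higher and 0 lower of 2, adjusted p = 0.412). The threshold was not reached by shoot green tissue markers (0 higher and 4 lower of 16, adjusted p = 0.0762) and xylem markers (1 higher and 0 lower of 2, adjusted p = 0.132). Further lists without a call were phloem markers (0 higher and 0 lower of 3, adjusted p = 0.809) and root cap markers (0 higher and 0 lower of 1, adjusted p = 0.579). Adjusted over the list alone, these counts were the same except 2 higher and 0 lower for xylem markers.

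For rises from 1 h to 3 h, the rule named ATHSP22.0 (at least 64.6-fold higher), UGT74E2 (from 0.761 ± 0.399 to 165 ± 16.7 CPM) and UGT75B1 (from 2.12 ± 1.08 to 186 ± 27.3 CPM). It also named DOGT1 (AT2G36800), a glucosyltransferase (107-fold higher, counting interval 29.3 to 886) and GSTU11 (AT1G69930) (55.1-fold higher, counting interval 15 to 460). For falls it named EXT6 (118-fold lower, counting interval 20.7 to 4710), EXT11 (47.6-fold lower, counting interval 12.7 to 400), EXT13 (44.4-fold lower, counting interval 11.9 to 374), NRT2:1 (41.9-fold lower, counting interval 13.9 to 207) and HRGP1 (from 27.7 ± 7.40 to 0.885 ± 0.619 CPM). The count of 1755 moved to 1140 without RB 3 h replicate a, with 663 higher and 477 lower. The authors' deposited table marked 993 genes between 3 h and 1 h, 581 higher and 412 lower at 3 h.

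In the combined RBH treatment at 2 h, all 22 heat shock and 23 of 26 detoxification genes were higher than in 1 h water. So were 11 of 22 jasmonate and 9 of 14 hypoxia genes, while all 4 root hair markers and 10 aquaporins were lower, and these 4 lists lost their camera call with an estimated correlation (adjusted p = 0.0938, 0.0665, 0.069 and 0.0938). GSTU12 rose from 1.48 ± 0.909 to 871 ± 101 CPM (log2 fold change 9.34, SE 0.46, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.25e-12). AOC2 (AT3G25770), an allene oxide cyclase of jasmonate synthesis, rose from 1.45 ± 1.43 to 92.4 ± 17.7 CPM (5.68, SE 0.45, adjusted p = 8.16e-10). In contrast LRL3 (AT5G58010), a root hair transcription factor, fell from 75.3 ± 6.10 to 2.55 ± 1.65 CPM (-5.33, SE 0.42, adjusted p = 5.37e-10). In all, 2671 genes were called, 1426 higher and 1245 lower, of which 1055 and 817 changed at least 2-fold.

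In RBH 22 of 22 heat shock genes rose (22 adjusted over the list alone, median 4.90, 4.77 with genes at their bound, camera adjusted p = 1.39e-57). Detoxification genes rose in 23 of 26 cases (24 adjusted over the list alone, median 4.38, 4.28 with genes at their bound, adjusted p = 6.93e-32). Singlet oxygen markers rose in 10 of 10 (10 adjusted over the list alone, median 2.44, adjusted p = 4.26e-14). WRKY and ZAT factors rose in 13 of 14 (13 adjusted over the list alone, median 2.19, 1.97 with genes at their bound, adjusted p = 8.64e-11). WRKY15 (AT2G23320) rose from 73.0 ± 8.14 to 361 ± 44.3 CPM and OPR1 from 113 ± 16.6 to 3026 ± 136 CPM. Of the ERF and DREB factors 14 of 19 rose and 1 fell (15 and 1 adjusted over the list alone, median 2.19, adjusted p = 6.36e-12). Salicylate and immunity genes rose in 11 of 12 (11 adjusted over the list alone, median 1.73, adjusted p = 2.68e-09). PAD3 rose from 3.18 ± 0.705 to 199 ± 35.8 CPM. These 6 calls held with an estimated correlation, at adjusted p = 0.00568 to 0.0262.

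Jasmonate genes rose in 11 of 22 cases in RBH (12 adjusted over the list alone, median 1.03, adjusted p = 0.00014, and adjusted p = 0.0938 with an estimated correlation). Hypoxia genes rose in 9 of 14 (10 adjusted over the list alone, median 1.55, adjusted p = 5.71e-05, and adjusted p = 0.0665 with an estimated correlation). ADH1 (AT1G77120), an alcohol dehydrogenase, rose from 7.19 ± 3.21 to 47.5 ± 5.92 CPM. Mitochondrial dysfunction genes rose in 8 of 9 (8 adjusted over the list alone, median 2.04, adjusted p = 0.000122, and adjusted p = 0.069 with an estimated correlation). All 10 aquaporins fell (10 adjusted over the list alone, median -1.30, adjusted p = 1.84e-08, and adjusted p = 0.0938 with an estimated correlation). PIP2;4 (AT5G60660) fell from 161 ± 20.3 to 28.7 ± 12.2 CPM. All 4 root hair markers fell too (4 adjusted over the list alone, median -4.26, adjusted p = 4.45e-05, and adjusted p = 0.069 with an estimated correlation). The camera test did not pass for auxin response and transport (2 higher and 5 lower of 18, adjusted p = 0.572) and abscisic acid and dehydration (6 higher and 1 lower of 16, adjusted p = 0.136). It also did not pass for the endoplasmic reticulum unfolded protein response (1 higher and 4 lower of 13, adjusted p = 0.116) and cytosolic ribosomal proteins (3 higher and 0 lower of 29, adjusted p = 0.491). No list call was made for ribosome biogenesis (0 higher and 0 lower of 11, adjusted p = 0.779) and proteases and cell death regulators (4 higher and 3 lower of 13, adjusted p = 0.599). The threshold was not reached by root nutrient uptake (6 higher and 7 lower of 14, adjusted p = 0.307) and antioxidant enzymes (6 higher and 2 lower of 18, adjusted p = 0.166). Further lists without a call were cell division (0 higher and 0 lower of 2, adjusted p = 0.961) and shoot green tissue markers (0 higher and 1 lower of 16, adjusted p = 0.877). The same was found for endodermis markers (0 higher and 0 lower of 5, adjusted p = 0.957) and xylem markers (2 higher and 0 lower of 2, adjusted p = 0.397). Likewise not called were phloem markers (0 higher and 1 lower of 3, adjusted p = 0.572) and root cap markers (0 higher and 0 lower of 1, adjusted p = 0.694). Adjusted over the list alone, these counts were the same except 7 higher and 1 lower for abscisic acid and dehydration, 0 higher and 0 lower for cytosolic ribosomal proteins, 4 higher and 4 lower for proteases and cell death regulators and 6 higher and 3 lower for antioxidant enzymes. Nutrient uptake had a negative median (-0.36) beside an upward test and shoot green tissue a positive one (0.19) beside a downward test. Median and mean differed in sign for auxin (-0.14 and 0.08) and for proteases and cell death (-0.03 and 0.45). In nutrient uptake LSU1 rose from 8.90 ± 6.14 to 1213 ± 207 CPM and APR1 (AT4G04610) from 58.4 ± 19.4 to 474 ± 66.7 CPM.

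In RBH the rule named for rises GSTU12, already described, HSP23.6-MITO (at least 197-fold higher), LHT7 (AT4G35180) (at least 76.2-fold higher), ATHSP22.0 (at least 70.7-fold higher), NHL25 (AT5G36970) (at least 34.4-fold higher), GSTU25 and HSP21 (AT4G27670) (both at least 28.4-fold higher), the bounds being over 0 counts in water. TDR1 (AT3G23230), the ethylene-response factor ERF98, was 530-fold higher (95% counting interval 95 to 21000). For falls in RBH it named LRL3, already described, NRT2:1 (409-fold lower, counting interval 139 to 1990), PME2 (AT1G53830), a pectin methylesterase (from 44.0 ± 6.37 to 1.61 ± 0.600 CPM) and LRX1 (AT1G12040), a leucine-rich extensin of root hairs (from 17.1 ± 2.59 to 0.861 ± 1.49 CPM). It also named EXPA7 (from 45.6 ± 2.91 to 2.47 ± 2.37 CPM), XTH14 (AT4G25820) (from 275 ± 26.8 to 17.7 ± 10.7 CPM), RHS19 and EXT13 (log2 fold changes -4.28 and -4.11). Without 1 library at a time the count of 2671 ran from 2133 to 2615. The authors' deposited table marked 1743 genes in RBH, 994 higher and 749 lower than in water.

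The comparison of RBH with RB at the same 2 h asked what the combined treatment adds, and H2O2 and the dye as named on the label changed together in it. Of the fixed lists, 9 of 22 jasmonate, 11 of 29 ribosomal protein and 5 of 14 hypoxia genes were higher in RBH, and 1 of 4 root hair markers was lower. These lists passed camera and lost the call with an estimated correlation (adjusted p = 0.27, 0.306, 0.306 and 0.533), root hair also with fry (0.0587) and with the shoot score (0.0668). AOC2 was 92.4 ± 17.7 CPM in RBH and 4.39 ± 3.36 in RB (log2 fold change 4.61, SE 0.38, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.97e-08), and PAD3 199 ± 35.8 and 22.4 ± 8.42 (3.12, SE 0.26, adjusted p = 1.74e-08). WRKY31 (AT4G22070) was lower, at 2.94 ± 1.07 against 27.7 ± 4.88 CPM (-3.43, SE 0.36, adjusted p = 6.01e-07). In all, 1660 genes were called, 971 higher and 689 lower in RBH, of which 507 and 479 changed at least 2-fold.

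No list call in this comparison held with an estimated correlation. Jasmonate genes were higher in 9 and lower in 1 of 22 (11 and 1 adjusted over the list alone, median 0.63, camera adjusted p = 1.58e-05, and adjusted p = 0.27 with an estimated correlation). AOC1 (AT3G25760) was at 47.4 ± 5.95 against 2.94 ± 1.05 CPM. Cytosolic ribosomal proteins were higher in 11 of 29 (15 adjusted over the list alone, median 0.45, adjusted p = 0.000215, and adjusted p = 0.306 with an estimated correlation). RPS6 (AT4G31700) was at 1680 ± 209 against 758 ± 229 CPM. Ribosome biogenesis genes were higher in 5 of 11 (5 adjusted over the list alone, median 0.74, adjusted p = 0.00269, and adjusted p = 0.306 with an estimated correlation). NUC-L1 was at 1067 ± 176 against 476 ± 68.8. Salicylate and immunity genes were higher in 7 and lower in 1 of 12 (8 and 3 adjusted over the list alone, median 0.86, adjusted p = 0.00463, and adjusted p = 0.306 with an estimated correlation). Hypoxia genes were higher in 5 and lower in 1 of 14 (6 and 1 adjusted over the list alone, median 0.88, adjusted p = 0.00491, and adjusted p = 0.306 with an estimated correlation). LBD41 (AT3G02550), a transcription factor, was at 182 ± 12.7 against 41.6 ± 4.25 CPM. Detoxification genes were higher in 8 and lower in 3 of 26 (10 and 4 adjusted over the list alone, median 0.41, adjusted p = 0.0259, and adjusted p = 0.533 with an estimated correlation, or 0.0587 with fry). UGT73B5 (AT2G15480) was at 1044 ± 85.7 against 316 ± 85.6 and UGT74E2 at 12.9 ± 3.04 against 73.5 ± 50.4 CPM. Root hair markers were lower in 1 of 4 (3 adjusted over the list alone, median -1.90, adjusted p = 0.0332, and adjusted p = 0.533 with an estimated correlation, 0.0587 with fry or 0.0668 with the shoot score).

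The camera test did not pass in this comparison for the heat shock response (4 higher and 3 lower of 22, adjusted p = 0.663) and singlet oxygen markers (0 higher and 1 lower of 10, adjusted p = 0.268). It also did not pass for WRKY and ZAT factors (2 higher and 1 lower of 14, adjusted p = 0.268) and ERF and DREB factors (4 higher and 2 lower of 19, adjusted p = 0.167). No list call was made for auxin response and transport (0 higher and 3 lower of 18, adjusted p = 0.129) and abscisic acid and dehydration (5 higher and 2 lower of 16, adjusted p = 0.272). The threshold was not reached by the endoplasmic reticulum unfolded protein response (6 higher and 1 lower of 13, adjusted p = 0.0741) and the mitochondrial dysfunction response (0 higher and 3 lower of 9, adjusted p = 0.165). Further lists without a call were proteases and cell death regulators (1 higher and 3 lower of 13, adjusted p = 0.126) and aquaporins (2 higher and 0 lower of 10, adjusted p = 0.787). The same was found for root nutrient uptake (5 higher and 2 lower of 14, adjusted p = 0.139) and antioxidant enzymes (2 higher and 1 lower of 18, adjusted p = 0.417). Likewise not called were cell division (0 higher and 0 lower of 2, adjusted p = 0.33) and shoot green tissue markers (1 higher and 0 lower of 16, adjusted p = 0.268). Also without a call were endodermis markers (1 higher and 0 lower of 5, adjusted p = 0.357) and xylem markers (0 higher and 0 lower of 2, adjusted p = 0.357). The test further left open phloem markers (0 higher and 1 lower of 3, adjusted p = 0.224) and root cap markers (0 higher and 0 lower of 1, adjusted p = 0.529). Adjusted over the list alone, these counts were the same except 5 higher and 3 lower for the heat shock response, 1 higher and 4 lower for singlet oxygen markers, 2 higher and 2 lower for WRKY and ZAT factors, 0 higher and 5 lower for auxin response and transport, 6 higher and 2 lower for abscisic acid and dehydration, 8 higher and 2 lower for the endoplasmic reticulum unfolded protein response, 0 higher and 4 lower for the mitochondrial dysfunction response, 3 higher and 1 lower for aquaporins, 5 higher and 3 lower for root nutrient uptake, 1 higher and 0 lower for cell division and 1 higher and 0 lower for xylem markers. The heat shock list had a negative median (-0.12) beside an upward test. In it Hsp70b was at 469 ± 130 against 145 ± 24.9 CPM, and AT5G51440, a mitochondrial small heat shock protein, lower at 137 ± 49.4 against 345 ± 105. Aquaporins had a median of -0.03 beside a mean of 0.06. ERD10 (AT1G20450) and KIN2 (AT5G15970), proteins of dehydration and cold, were higher (1302 ± 247 against 550 ± 75.3 and 1565 ± 67.3 against 811 ± 153 CPM), and IAA7 (AT3G23050), an auxin repressor, was lower (69.6 ± 18.5 against 178 ± 36.6). CASP1 of the endodermis was higher (397 ± 99.4 against 210 ± 23.4), and SUC2 (AT1G22710), a sucrose transporter of the phloem, lower (62.1 ± 23.8 against 136 ± 12.5).

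For rises in RBH over RB the rule named PMAT2 (AT3G29670), a malonyltransferase (109-fold higher, counting interval 29.9 to 901), DDF1 (AT1G12610), a transcription factor of the DREB family (from 1.54 ± 0.526 to 63.5 ± 11.6 CPM) and its paralog ddf2 (AT1G63030) (53.7-fold higher, counting interval 9.38 to 2150). Also named were ERF14 (AT1G04370) (from 0.702 ± 0.830 to 31.7 ± 5.34 CPM) and AOC2, whose counts could be shared with AOC1. For falls in RBH below RB it named PME2 (log2 fold change -3.93), LECRKA4.2 (AT5G01550), a lectin receptor kinase (from 21.7 ± 6.25 to 1.37 ± 0.586 CPM), WRKY31, LRL3 (from 16.9 ± 2.34 to 2.55 ± 1.65 CPM) and EXPA7 (from 11.6 ± 4.76 to 2.47 ± 2.37 CPM). The call of EXPA7 was lost without RBH replicate c (adjusted p = 0.0524, with 0.000258 to 0.0524 over all alternatives). The count of 1660 moved to 1077 without RBH replicate c (661 higher and 416 lower) and to 1067 with only the 2 groups in the fit (668 and 399). It was 1126 without RB 2 h replicate b (687 and 439), 1168 without RB 2 h replicate c (709 and 459) and 1129 when thinned (627 and 502). The authors' deposited table marked 847 genes, 479 higher and 368 lower in RBH.

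Many genes changed the same way in more than 1 comparison with water. At 1, 2 and 3 h of RB, 278 genes were higher and 194 lower at each time, where independent lists would share 6.19 and 4.62, and 391 of these also changed the same way in RBH (236 higher, 155 lower, against 0.893 and 0.582). RB 2 h and RB 3 h shared 1099 higher and 1083 lower genes (201 and 200 if independent). RB 2 h and RBH shared 804 higher and 672 lower (180 and 152 if independent), and 29 went in opposite directions. The 3 water libraries are common to these comparisons and were not split between them, so part of the excess may come from them. In 20 simulations of unchanged groups against shared water libraries 0 genes were shared, but a comparison held at most 2 calls, so this does not measure what the shared libraries add. The log2 fold changes of RB 2 h and RBH had a covariance of 1.11 across genes (0.122 simulated) and r = 0.788 (0.573 simulated), where genes are not independent replicates.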

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

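Tests chosen after seeing their results were the swap of libraries, both root hair tests, the 20 repeated draws and the comparisons of adjacent times. Others were, for RBH against RB, the thinned count and that without a library. A tested difference between exposure times or between the combined treatment and RB marked each result here. Between RBH and RB at 2 h, 1660 genes were called, and 29 genes went in opposite directions against water. Between times of RB, 1755 genes were called for 3 h against 1 h, 968 for 2 h against 1 h and 22 for 3 h against 2 h. Lists that passed camera between RBH and RB had medians of 0.41 (detoxification), 0.63 (jasmonate), 0.45 (ribosomal proteins), 0.74 (ribosome biogenesis), 0.86 (salicylate and immunity), 0.88 (hypoxia) and -1.90 (root hair). All 7 lost the call with an estimated correlation (adjusted p = 0.533, 0.27, 0.306, 0.306, 0.306, 0.306 and 0.533), detoxification and root hair also with fry (0.0587 each), and root hair with the shoot score (0.0668). Between 3 h and 1 h, the lists that passed camera and held with an estimated correlation had medians of 3.06 (heat shock), 2.82 (detoxification), 1.92 (mitochondrial dysfunction), 1.34 (ERF and DREB), 1.20 (singlet oxygen), 1.05 (salicylate and immunity) and -1.86 (aquaporins). The call was lost with an estimated correlation for WRKY and ZAT (median 0.99, adjusted p = 0.0942), jasmonate (0.80, 0.174), hypoxia (0.55, 0.191), nutrient uptake (0.27, 0.191) and ribosome biogenesis (-0.47, 0.255). The same held for endodermis (-0.74, 0.121), root hair (-3.26, 0.0857) and the unfolded protein response (-0.49, 0.327), which also lost it with the replicate block (0.0505), without the 2 libraries apart (0.207) and with the shoot score (0.0968).

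Pattern 1 weighed was the position of RB 1 h replicate b and RB 2 h replicate a on principal component 3. A swap of these 2 libraries was argued against, since each held the heat shock level of its own group, with a smaller gap of 2 log2 CPM (4.88 beside 4.54 and 5.11 at 1 h, 7.20 beside 6.88 and 7.46 at 2 h). Thinning every library to the smallest total left the nearer of the 2 at 1.05 times the farthest other library (2.50 at full depth), with 0.897 to 1.76 over the 20 draws and 1.18 to 6.71 over resampled genes at full depth, so depth cannot be told apart from other causes. The ratio was the highest over components 1 to 4, on component 3 at full depth and on component 4 when thinned, so the 2 values are not from the same component. The draws changed the reading of this test. Shoot tissue stays open too, at a ratio of 1.12 (0.968 to 1.24) after the shoot score was regressed out, on component 3. No biological explanation was tested.

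Pattern 2 was the lower level of root hair genes after RB. On a wider list of 18 genes, 12 tested, RB 3 h had 9 lower and 0 higher than water, with a median of -3.04 and a range of -4.93 to 0.64. A loss of hair cells cannot be told apart from lower expression, since the heterogeneity chi-square per degree of freedom of 22.5 shows unequal falls, which lost cells with some expression elsewhere would also give. Time in solution and an effect of the dye stay open, and the design cannot part them. At 1 h 0 members were lower (median -0.22), and water had a single time, 1 h by the labels.

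Pattern 3 was the difference between RBH and RB at 2 h. Unequal totals were argued against (1129 genes when thinned), but depth-linked composition stays open. Most calls did not need RB 2 h replicate a, which lay apart, with 1483 of 1660 also made without it. Shoot tissue stays open, since the shoot score as deviations from group means (1760 genes called) keeps group differences. A biological difference stays a hypothesis, in which H2O2 and the dye named on the label changed together.

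In other splits of the same 6 libraries into 3 and 3, the highest count of genes was 1 beside 533 for RB 1 h vs water, 0 beside 2451 for RB 2 h, 0 beside 3238 for RB 3 h, 0 beside 2671 for RBH, 1 beside 1660 for RBH against RB, 0 beside 1755 for 3 h against 1 h, 1 beside 968 for 2 h against 1 h, and 0 beside 22 for 3 h against 2 h. In each, only the real split of 10 was as large. For lists, the highest other count was 10 beside 10 for RB 1 h (2 splits as large), 9 beside 14 for RB 2 h (1), 13 beside 12 for RB 3 h (4), 12 beside 11 for RBH (5), 7 beside 7 for RBH against RB (3), and 14 beside 15 for 3 h against 1 h (1). The splits cannot decide, since mixing groups puts any difference into the spread and 10 give no value under 0.1.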

How the results depend on the processing

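Fits without the 2 libraries apart, organelle genes or the 100 most abundant genes, or with the shoot score, were chosen after seeing the data. The cause of each difference below was not tested. Against the chosen settings, 118 counts of genes or lists stayed within 1.5 times, 16 were lower and 4 higher. For single genes, 3316 results kept their side of the test, 90 lost the call, 19 gained it and 9 turned direction, and for list tests the numbers were 816, 50 lost and 34 gained. Fits without 1 library gave 296 to 765 genes for RB 1 h vs water, 1707 to 2657 for RB 2 h, 2486 to 2778 for RB 3 h, 2133 to 2615 for RBH, 1077 to 1952 for RBH against RB and 1140 to 1588 for 3 h against 1 h. A group left with 2 libraries shared the spread of the others. Without the 2 libraries apart, RB 1 h gave 1104 genes and RBH against RB 11 lists. With only the compared groups, RBH against RB gave 1067 genes. With an absolute log2 fold change of at least 1 required, 1606 genes remained for RB 2 h, 2137 for RB 3 h, 986 for RBH against RB and 1115 for 3 h against 1 h. With an estimated correlation the lists called were 2 for RB 1 h, 7 for RB 2 h, 8 for RB 3 h, 6 for RBH, 0 for RBH against RB and 7 for 3 h against 1 h, and with fry 20 for RB 3 h and 17 for RBH.

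The genes that turned direction were not called in the chosen fit. SMB in RB 2 h vs water was 0.105 when thinned and -0.368 to 0.227 without 1 library, APL in RB 2 h vs water -0.130 to 0.171 (-0.055 without water b, -0.044 without water c, -0.130 without RB 2 h b), and SUC2 in RB 2 h vs water -0.003 (without RB 2 h a) to 0.167, with -0.006 without the 2 libraries apart. CDKB2;1 in RBH 2 h vs RB 2 h was -0.099 when thinned, and SEOR1 in RBH 2 h vs RB 2 h -0.278 to 0.017 without 1 library. Each other setting is given for RB 1, 2 and 3 h, RBH, RBH against RB and 3 h against 1 h in turn. DESeq2 called 603, 2259, 2982, 2535, 1518 and 1593 genes, RLE scaling 545, 2463, 3222, 2695, 1662 and 1768, and no filter 510, 2352, 3235, 2770, 1698 and 1718. With the replicate letter as a block the counts were 417, 2203, 2985, 2456, 1434 and 1545, and thinned to the smallest total 483, 1942, 2563, 2164, 1129 and 1352. With the shoot score, which here keeps group differences, they were 624, 2572, 3467, 2850, 1760 and 1952. Leaving out organelle genes gave 534, 2454, 3239, 2680, 1662 and 1765, leaving out the 100 most abundant genes 514, 2389, 3150, 2664, 1609 and 1731, and leaving out the 2 libraries apart 1104, 2869, 3690, 3044, 2235 and 1697. Only the compared groups gave 597, 2010, 3795, 2668, 1067 and 1860. The filter of 10 CPM in 3 libraries gave 553, 2309, 3035, 2501, 1610 and 1715, and it changed RBH against RB from 971 higher and 689 lower to 815 and 795.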

Other observations

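The genes and tests in this part were all chosen after the values were seen. Of the genes called at 1 h of RB, fewer were called in the opposite direction at 3 h against 1 h than in the same direction. Of the genes higher at 1 h of RB than in water, 13 were lower at 3 h than at 1 h and 154 higher still, and of those lower at 1 h, 16 were higher at 3 h and 98 lower still. Independent calls with the same counts would share 25.4, 28.6, 21.5 and 19.1 genes in that order. Both comparisons use the same 3 RB 1 h libraries, so a deviation of these libraries alone gives opposite directions. The genes below are examples and no return toward water was tested. RBOHA (AT5G07390), an NADPH oxidase that makes superoxide, went from 0.986 ± 1.25 CPM in water to 6.851 ± 1.1 at 1 h, 2.49 ± 0.503 at 2 h and 1.48 ± 1.32 at 3 h. BMY3 (AT5G18670), a beta-amylase, went from 69.9 ± 11.3 to 133 ± 41.8, 64.6 ± 27.5 and 39.5 ± 5.64, and GAT1_2.1 (AT1G15040), a glutamine amidotransferase, from 4.63 ± 2.48 to 39.8 ± 11.4, 36.7 ± 9.11 and 20.6 ± 7.36. Of those lower at 1 h and higher at 3 h, 2 are given as examples. CYP79B2 (AT4G39950) went from 524 ± 77.7 to 256 ± 99.5, 646 ± 115 and 966 ± 138, and CYP83B1 (AT4G31500) from 949 ± 118 to 561 ± 126, 956 ± 115 and 948 ± 80.4. At 3 h GAT1_2.1 was still higher than in water (log2 fold change 2.18, adjusted p = 0.000159), BMY3 was lower (-0.82, adjusted p = 0.0196) and CYP79B2 higher (0.88, adjusted p = 0.0039).

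Of the 29 genes with opposite directions in RB 2 h and RBH against water, 15 were lower in RB and higher in RBH. Among them were 2 S-adenosylmethionine synthetases, MAT3 (AT2G36880) (1061 ± 36.2 CPM in water, 686 ± 62.8 in RB 2 h and 1637 ± 233 in RBH) and MTO3 (AT3G17390) (1351 ± 105, 966 ± 202 and 1890 ± 114), and PMT5 (AT3G18830), a polyol transporter (82.6 ± 1.63, 53.7 ± 5.87 and 207 ± 37.3). The other 14 were higher in RB and lower in RBH, with the expansin-like EXLB1 (AT4G17030) (94.5 ± 4.02, 202 ± 35.9 and 58.8 ± 3.51) and TDT (AT5G47560), the malate transporter of the vacuole (98.8 ± 31.0, 195 ± 42.0 and 59.8 ± 10.0). BMY3 was at 319 ± 28.7 CPM in RBH.

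Within groups, libraries with a larger total had a smaller share of ATMG00020. Over 15 libraries as deviations from their group means, 3 relations with log2 total were tested with 7776 permutations within groups, two-sided. For the log2 share of ATMG00020 Pearson r was -0.90 (p = 0.000386, adjusted p = 0.00116), Spearman rho -0.92 (p = 0.000643, adjusted p = 0.00193), and r -0.86 without the 2 farthest libraries. For the share of the 10 most abundant genes r was -0.83 (p = 0.00141, adjusted p = 0.00212), rho -0.86 (p = 0.00154, adjusted p = 0.00231), and r -0.81 without the 2 farthest. For the shoot score r was 0.24 (p = 0.549, adjusted p = 0.549), rho 0.16 (p = 0.654, adjusted p = 0.654), and r 0.01 without the 2 farthest. Correlations of log2 CPM between libraries ran from 0.921 to 0.974 within groups and from 0.814 to 0.973 between groups.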
